A study of Caenorhabditis elegans with 4 samples.

How the data were processed

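The data are peak lists from anti-GFP chromatin immunoprecipitation with sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites at the fourth larval stage (L4). Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and quenched with 100 mM Tris. Chromatin was sonicated, and the fragments bound to a GFP-tagged transcription factor were collected with an affinity-purified goat antibody against EGFP. Part of each lysate was kept as input, the total genomic DNA that serves as control. The labels name 2 ChIP and 2 input samples, numbered 1 and 2 in each group. Samples were grouped by their titles. The labels disagree on 2 points. The titles name the factor CEH-28, whereas the strain, genotype and design text name strain OP241 with a tagged ceh-38 gene, so the text speaks of the tagged factor. The free-text descriptions of the input and ChIP samples also appear exchanged, the antibody being listed under the samples titled as input.

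There were 3 peak lists. ChIP replicate 1 and ChIP replicate 2 have a list each, and the authors deposited a further list for the whole series, named as combined. How the combined list was made from the replicates is not given in the sources used here. No list of the input samples was used here. Per the file headers, coordinates are on WormBase build WS180 and the peaks were called with PeakSeq, a caller that scores regions of ChIP reads against a control. Each peak has a start, an end and a q-value, the caller's p-value corrected for multiple testing. Per the file headers, this q-value is the only measurement per peak, and it is given in the score field and again as an attribute, with the same text in every row of all 3 lists. The aligner, the read filters, the q-value limit and the PeakSeq version are not given in the sources used here. The lists hold no read counts, heights or summits, so the sequencing depth behind each peak is unknown and no interval could be drawn from reads.

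A q-value describes how surely a region stands out from the control in that list. It falls with depth as well as with enrichment, so q-values were compared by rank within a list and not as binding strength between lists. Neighbouring peaks of a list lie at least 200 bp apart, so closer regions form 1 peak. Values are printed as q or as −log10 q computed from the deposited text, because the smallest q-values lie below the normal range of double-precision numbers. No peak of any list has a q-value of 0.

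Peaks of 2 lists were called shared when they overlapped by at least 1 bp. The number shared was set against 10000 random placements of the peaks within their own chromosomes with widths kept (one-sided test, smallest possible p 1e-04). Shares have 95% Wilson intervals, and peaks per Mb have exact 95% Poisson intervals. Both cover counting error over peaks only. Across peaks that overlap one to one, Spearman and Pearson correlations of −log10 q were tested with 100000 two-sided permutations (smallest possible p 1e-05), with Benjamini-Hochberg adjustment over 6 relations. Peaks are not independent replicates. Chromosome lengths of build WS180 were not used here, so the span of each chromosome was taken from base 1 to the end of its last peak in any list. Peak numbers per chromosome were compared with these spans by a chi-square test. Chromosome X was compared with the autosomes, and chromosome III with the other autosomes, by two-sided exact binomial tests. The share of peak centres in the outer 25% at either end of the spans was tested against 50% in the same way. The comparisons of chromosome III and of the outer parts were chosen after the peak positions had been seen. All these tests take peaks as units and describe the placement of peaks. The tests and intervals treat peaks as independent of each other, whereas peaks lay in clusters, so the p-values are too small and the intervals too narrow. With 2 samples of 1 group, not stated to come from separate cultures, they say nothing of the spread between animals or cultures.

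Before the data were examined, the regions to be named were set as the 20 combined-list peaks with the smallest q-values among those that overlap a peak in both replicates, plus the genes ceh-38 and ceh-28 and the other cut homeobox genes. The planned results on 3 further questions, the share of peaks near gene starts, the binding of gene lists and the enrichment of motifs, could not be computed: no genome or annotation of build WS180 was used here. The gene table at hand is of assembly WBcel235, another build, so it served only to count protein-coding genes per chromosome and to look up the chromosome of ceh-38 and ceh-28. Peaks are therefore named by position, and none is assigned to a gene. The alternatives were another overlap rule, lists of equal length, the better part of each list, a single replicate's list, a local random shift, peaks per gene, joining of neighbouring peaks, and restoring regions that a list lacks.

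The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data. Of 60 pairs of randomly placed lists of the replicates' size, 1.7% were called shared. Of 300 planted shared peaks among 906, 280 were recovered above chance, and randomly placed lists of 3766 peaks had 50% of them in the outer parts.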

Results

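ChIP-seq peaks of a GFP-tagged homeodomain transcription factor were compared in L4 hermaphrodites of C. elegans. The strain label names OP241, which carries a tagged copy of ceh-38. CEH-38 belongs to the ONECUT family of cut homeodomain proteins, whereas CEH-28, the factor in the sample titles, is a homeodomain protein of the NK-2 class. The design text gives the purpose as mapping where the tagged factor binds in the living animal. ChIP replicate 1 gave 2778 peaks, ChIP replicate 2 gave 906, and the combined list held 3766. No peak list of the 2 input samples was used here, so no value in control chromatin could be set beside the peaks. Peaks covered 1405 kb in replicate 1, 625 kb in replicate 2 and 1837 kb in the combined list, which is 1.84% of the chromosome spans. The median peak width was 351 bp (quartiles 243 and 593 bp) in replicate 1, 480.5 bp (319 and 809 bp) in replicate 2 and 340 bp (227 and 576.5 bp) in the combined list. Each peak carries a q-value from the authors' peak caller. The largest q-value listed was 3.83e-04, 2.73e-04 and 4.39e-04, respectively. Of the combined-list peaks, 82 were narrower than 50 bp, against 22 in replicate 1 and 1 in replicate 2.

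Nearly all regions of the shorter replicate list were present in the longer one. Of the 906 peaks of replicate 2, 858 overlapped a peak of replicate 1 (94.7%, 95% interval 93.0 to 96%). Random placement gave a mean of 34.4 ± 5.63 overlaps (SD over 10000 placements) and at most 56, so the observed number was 24.9 times the random mean (one-sided permutation test of peak positions, p = 1e-04, the smallest it can give). In the other direction, 821 of the 2778 replicate 1 peaks overlapped a peak of replicate 2 (29.6%, 27.9 to 31.3%), against a random mean of 35.2 ± 5.90 (the same permutation test, p = 1e-04). With replicate 1 limited to its 906 smallest q-values, 701 of them were found in replicate 2 (77.4%, 74.5 to 80.0%).

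In replicate 1, the share of peaks found in replicate 2 fell from the smallest q-values to the largest. All 277 peaks at ranks 1 to 277 of replicate 1 were found in replicate 2 (100%, 98.6 to 100%), and 251 of the 278 at ranks 278 to 555 (90.3%, 86.2 to 93.2%). The share was 55% (49.2 to 60.8%) at ranks 556 to 833, 12.2% (8.89 to 16.6%) at ranks 1112 to 1389 and 0.719% (0.198 to 2.58%) at ranks 2501 to 2778. In the other direction, the best-ranked peaks of replicate 2 were an exception: 23 of its 50 best (46%, 33 to 59.6%) had no counterpart among the peaks of replicate 1, against 5 of the 350 at ranks 51 to 400 (1.43%, 0.612 to 3.30%). The read depth of the libraries is unknown, so a replicate 1 region without a replicate 2 peak was not detected there and cannot be called unbound.

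**Figure D1:**
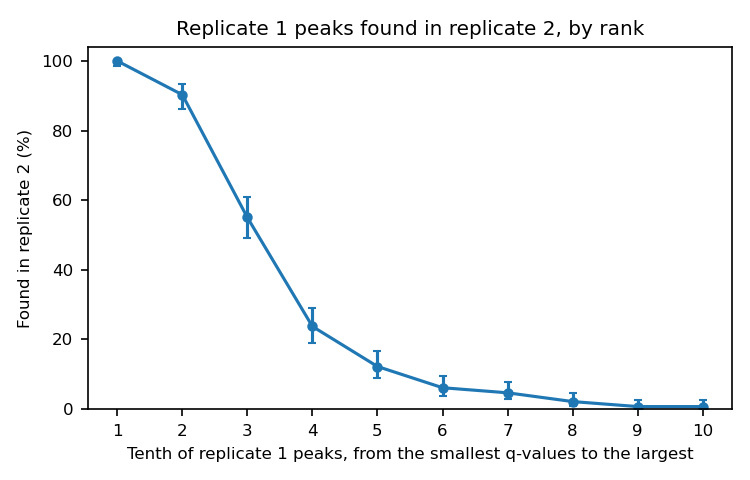
Share of replicate 1 peaks that overlap a replicate 2 peak (percent, vertical axis) for 10 about equal parts of the replicate 1 list, ordered from the smallest q-values to the largest (horizontal axis), with 95% Wilson intervals as bars. The share is 100% in the best part, 55% in the third and 0.719% in the last.

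Among the regions matched between the replicates, those with small q-values in one had small q-values in the other. Across 780 peaks that matched one to one, Spearman's rho of −log10 q was 0.878 and Pearson's r was 0.982 (two-sided permutation test, adjusted p = 1e-05 for both, the smallest possible). The q-values themselves differed in scale: the median −log10 q of these peaks was 19.9 in replicate 1 and 7.19 in replicate 2. The ratio of replicate 2 to replicate 1 had a median of 0.397 (quartiles 0.327 and 0.486), and replicate 2 had the smaller q-value in 10 of the 780 pairs. These correlations run across peaks, which are not independent replicates, and leave out unmatched peaks, among them 23 of the 50 best of replicate 2.

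**Figure D2:**
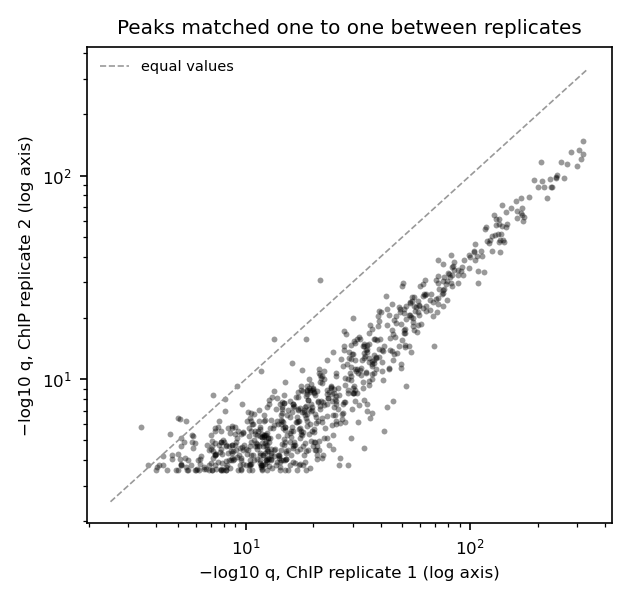
−log10 q of the 780 peaks matched one to one between ChIP replicate 1 (horizontal log axis) and ChIP replicate 2 (vertical log axis); each point is a peak and the dashed line marks equal values. The points rise together (Spearman's rho 0.878), and all but 10 lie below the line.

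The combined list contained a core of wide regions found in both replicates and a large set of narrow, weaker ones. Of its 3766 peaks, 798 overlapped peaks of both replicates (21.2%, 19.9 to 22.5%), with a median width of 817.5 bp and a median q of 1.62e-29. A further 1717 (45.6%, 44 to 47.2%) overlapped replicate 1 only, with a median width of 338 bp and a median q of 9.59e-08. Only 13 (0.345%, 0.202 to 0.590%) overlapped replicate 2 only. The remaining 1238 (32.9%, 31.4 to 34.4%) overlapped neither, with a median width of 233 bp and a median q of 6.38e-05. Conversely, 2557 of the replicate 1 peaks (92.0%, 91.0 to 93.0%) and 863 of the replicate 2 peaks (95.3%, 93.7 to 96.5%) were in the combined list. Of the 43 replicate 2 peaks not in the combined list, 34 were among the 50 best of replicate 2. Replicate 1 also lacked 23 of these regions, so the 13 peaks found in replicate 2 only leave out strong replicate 2 regions. In the better part of the combined list by q-value, 1883 peaks, the share found in both replicates was 42.1%, an alternative chosen after seeing the data. The combined list is not independent of the replicates, so its overlap with them was not tested.

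Peaks per Mb were densest on chromosome III and sparsest on chromosome X. The combined list held 943 peaks on III, or 68.5 peaks per Mb (95% interval 64.2 to 73.0), and 410 on X, or 23.3 per Mb (21.1 to 25.6). Chromosome I had 49.2 per Mb (45.7 to 52.9), IV had 36.7 (34 to 39.7), V had 29 (26.7 to 31.4) and II had 28.2 (25.6 to 31). The interval of X overlapped that of II in each list and that of V in each replicate. The 6 chromosomes differed from an even density (chi-square 575, 5 degrees of freedom, p = 4.42e-122). Because peaks lay in clusters, this p-value and those that follow are too small. The density on X was 0.571 of that on all autosomes together, the dense III included (exact binomial test, p = 1.49e-30). By the same exact test, the ratio was 0.545 in replicate 1 (p = 3.61e-26) and 0.477 in replicate 2 (p = 1.57e-12). Chromosome III had 1.95 times the density of the other autosomes (exact binomial test, p = 1.19e-60), with 2.17 in replicate 1 and 2.18 in replicate 2. Per 100 protein-coding genes, III was again the highest in the combined list with 35.7 peaks, whereas X with 15 lay above II with 12.5 and V with 12.1. Peaks on X were not narrower: their median width was 445.5 bp, against 287 bp on III. The best-ranked X peak, at 8035570 to 8037064, was in all 3 lists and held place 46, 45 and 48 in the combined list, replicate 1 and replicate 2. Of the 100 best combined-list peaks, 5 were on X. The comparison of III and the X peak named here were chosen after the values were seen.

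**Figure D3:**
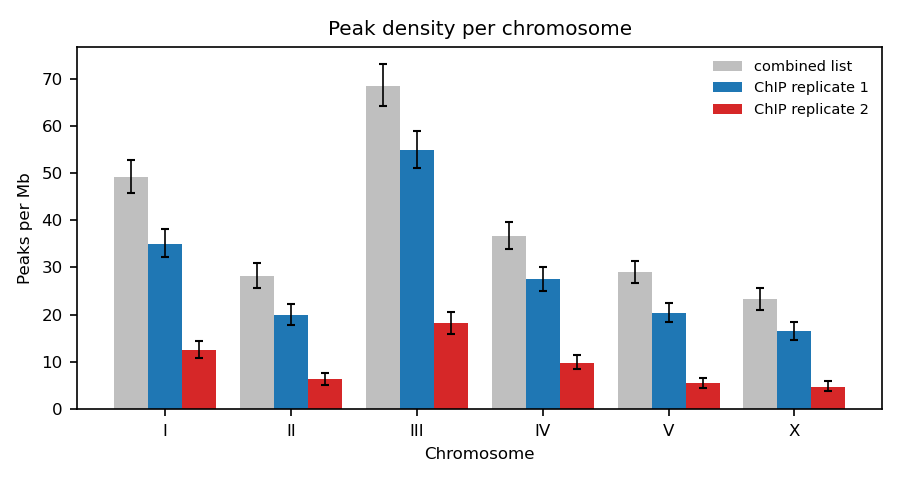
Peaks per Mb of chromosome span (vertical axis) for each chromosome (horizontal axis) in the combined list and in ChIP replicates 1 and 2; bars start at 0 and error bars are exact 95% Poisson intervals over peaks. Chromosome III is the densest in each list (68.5 per Mb in the combined list). X has the lowest value (23.3 per Mb), but its interval overlaps that of II in each list and that of V in each replicate.

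With both ends of each chromosome counted together, peaks gathered towards the ends, a comparison chosen after the positions were seen. Of the combined-list peaks, 2228 lay in the outer 25% at either end (the outer parts; 59.2%, 57.6 to 60.7%, against 50% for even placement; exact binomial test, p = 2.09e-29). The share was 62.2% (60.4 to 64%) in replicate 1 and 73.1% (70.1 to 75.9%) in replicate 2. Chromosome I had the highest share in the combined list (65.9%, 62.4 to 69.2%, adjusted p = 2.61e-17 by exact binomial tests over 6 chromosomes) and X the lowest (55.6%, 50.8 to 60.3%, adjusted p = 0.0261). On X, neither replicate passed the test alone (exact binomial test, p = 0.142 with 54.5% in replicate 1 and p = 0.156 with 58.3% in replicate 2). The ends of some chromosomes were unequal. On IV, the left outer part held 261 peaks and the right 117 (exact binomial test, adjusted p = 5.77e-13). On V, the left outer part held 127 and the right 211 (adjusted p = 1.71e-05 by the same exact test). Chromosome I had more peaks on the left, 275 against 213 (adjusted p = 0.01 by the same exact test). These 3 differences passed the test in each replicate, and III passed it in replicate 2 alone, with 116 on the left and 60 on the right (exact binomial test, adjusted p = 4.47e-05). The right end of IV, with 18.4% of the peaks of that chromosome, and the left end of V, with 21%, lay below the 25% of even placement in the combined list, and both did so in each replicate. On IV, the left and right outer parts held 224 and 87 peaks in replicate 1 and 107 and 21 in replicate 2. On V, they held 91 and 155, and 21 and 64. The fullest 1 Mb bins of the combined list were from 1 to 2 Mb on III with 97 peaks, from 3 to 4 Mb on III with 95, and from 1 to 2 Mb on I with 95. On V, the fullest bin of replicate 2 ran from 19 to 20 Mb and held 36 of its 115 peaks on that chromosome.

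**Figure D4:**
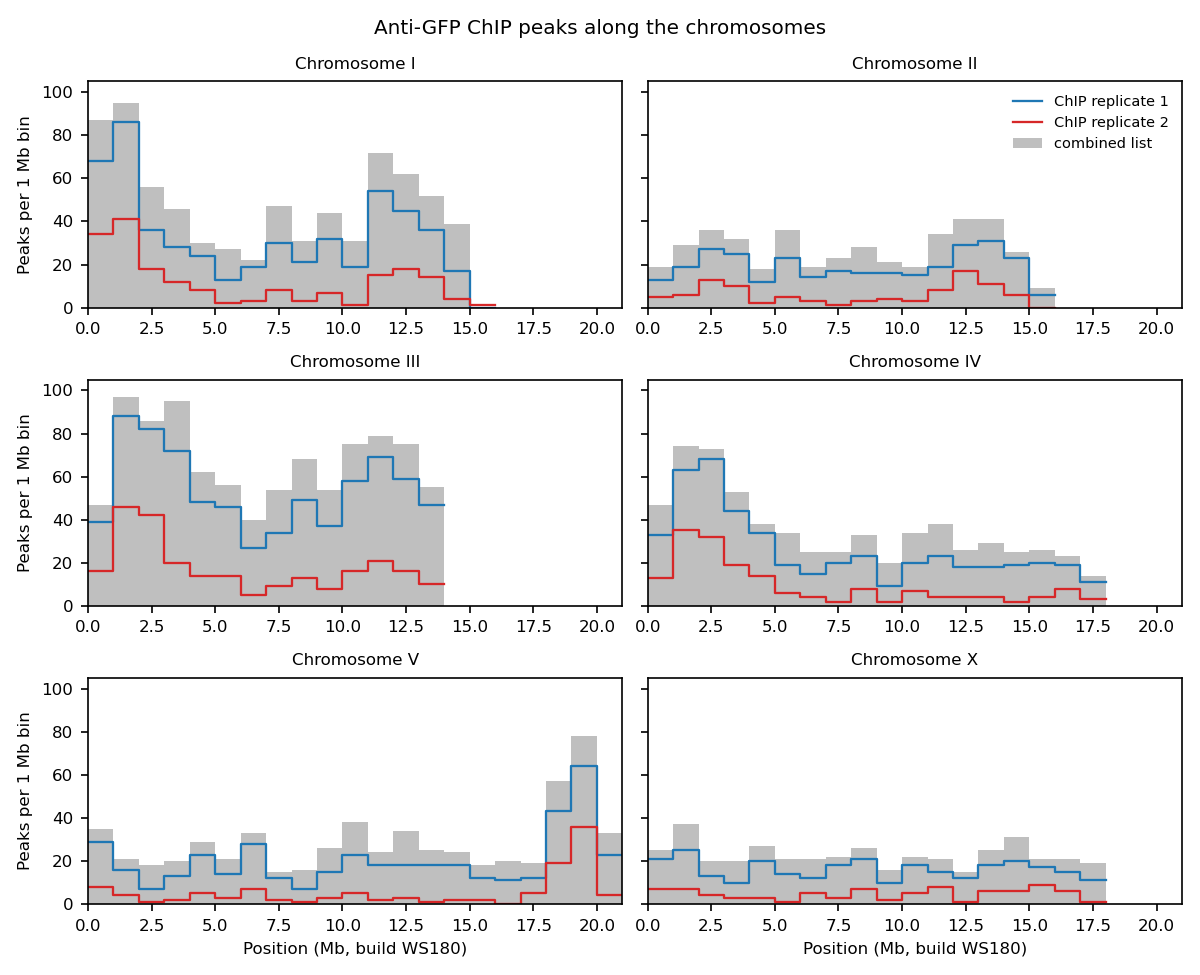
Number of peaks per 1 Mb bin (vertical axis) along each chromosome (horizontal axis, Mb on build WS180) for the combined list (grey bars) and ChIP replicates 1 and 2 (blue and red lines). The fullest combined-list bin, from 1 to 2 Mb on III, holds 97 peaks, and the fullest on X, from 1 to 2 Mb, holds 37.

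The 20 best-ranked combined-list regions found in both replicates lay on autosomes, all of them in the outer parts. There were 7 on chromosome III, 5 on I, 5 on IV, 2 on II, 1 on V and 0 on X. Their widths ran from 918 to 3998 bp, with a median of 2344 bp. The region with the smallest q was on III at 1467863 to 1469361 (q = 2.96e-323), with q = 3.71e-227 in replicate 1 and 5.70e-97 in replicate 2. It was followed by IV at 847467 to 850344 (q = 1.43e-315), I at 2935629 to 2938067 (q = 4.68e-308), III at 11220744 to 11223829 (q = 1.87e-304) and I at 11362100 to 11366097 (q = 7.36e-304). On II the best was at 3066258 to 3069099 (q = 2.58e-271), and on V at 19629319 to 19630918 (q = 1.97e-248). All 20 were among the 62 best peaks of replicate 1 and the 118 best of replicate 2, yet the best place any of them held in replicate 2 was 28. Of the 50 best replicate 2 peaks, 34 had no counterpart among the peaks of the combined list and 23 had none in replicate 1. The first of these, on I at 15064019 to 15067635 (q = 1.08e-256), was present in replicate 2 only. It is named because of its place and was chosen after its values were seen. Gene content of these regions, and of ceh-38, ceh-28 and the other cut homeobox genes, was not analysed here.

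The widest peak lay in the same region of chromosome II in all 3 lists. In the combined list it ran from 6939198 to 6962498, or 23301 bp, 4.12 times the width of the next widest peak. In replicate 1 it ran from 6939183 to 6961050 (21868 bp), 3.10 times the next. In replicate 2 the widest peak, from 6950066 to 6956992 (6927 bp), lay inside it and was 1.36 times as wide as the next, of 5088 bp. Its q-values were moderate: 4.24e-20 in the combined list (place 583), 3.56e-22 in replicate 1 (place 405) and 1.31e-31 in replicate 2 (place 120). The next widest combined-list peak, of 5654 bp, ended 1222 bp to its left. The region was chosen after its values were seen.

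**Figure D5:**
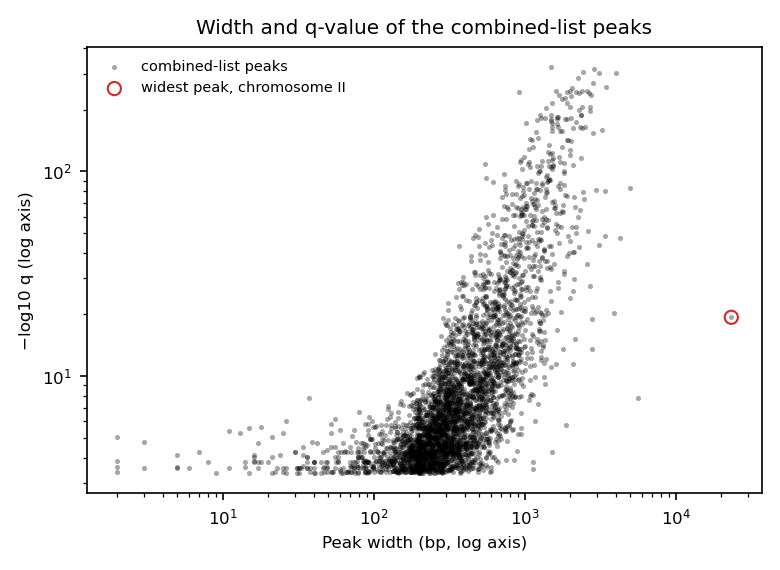
Width in bp (horizontal log axis) and −log10 q (vertical log axis) of each of the 3766 combined-list peaks; the red circle marks the widest peak, on chromosome II. That peak is 23301 bp wide with −log10 q of 19.4, far to the right of peaks with like q-values.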

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

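The alternatives on restored best peaks, joined peaks, chromosome III, the outer parts of chromosomes, the 50 best replicate 2 peaks and the better part of the combined list against both replicates were chosen after seeing the data. All 31 alternatives to tested results (replicate sharing, q correlation, X, chromosome III, outer parts) kept their direction and passed the test. Sharing of replicate 2 peaks ran from 75.7% (reciprocal overlap of 50%) to 97.1% (without its 50 best peaks). The ratio of X to autosomes ran from 0.477 (replicate 2 alone) to 0.772 (per protein-coding gene), that of chromosome III from 1.72 (peaks under 5 kb apart joined) to 2.18 (replicate 2 alone), and the share in the outer 25% at either end from 55% (joined) to 73.1% (replicate 2 alone). With peaks under 5 kb apart joined, exact binomial tests gave larger p-values: 3.46e-09 for X (ratio 0.714), 9.65e-26 for III and 7.78e-07 for the outer parts. Of 7 untested alternatives, 5 moved the value. The combined count of 3766 fell to 1883 in its better part, fixed by construction, and the lists of a single replicate held 906 (without replicate 1) to 2778 peaks. The share of combined peaks found in both replicates was 15.5% with reciprocal overlap and 17.4% with centres within 200 bp, both stricter rules, and 42.1% in the better part of the list, where the weaker peaks are left out. Leaving out a replicate meant using the other's own list, since a combined list could not be remade from peaks. No paired analysis was possible because the input samples, which share the replicate numbers, have no peak values used here, and the results come from no fit between groups. Alternatives on gene starts, gene lists and motifs were not run for lack of build WS180. Unknown read depth limits every statement on regions found in 1 list only.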

Other observations

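All tests in this part were chosen after the positions and q-values of the peaks had been seen, those on joined neighbouring peaks before the joined values were computed. Peaks lay in clusters. In the combined list, 53.3% of peaks had another within 5 kb, against 36.8% on average and at most 39.8% in 1000 random placements within chromosomes (permutation test of positions, p = 1e-03, the smallest it can give). With each peak kept in its own 1 Mb bin, so that the density along the chromosome stayed, random placement gave 39.0% on average and at most 41.6% (the same permutation test, p = 1e-03). In replicate 2, where peaks are sparser, 39.7% had a neighbour, against 11.9% within chromosomes and 17.8% within bins. Part of the excess can be regions split into several peaks, which random placement does not reproduce. For example, the replicate 1 peak on X at 8016623 to 8023673 was split in the combined list, into 8016631 to 8020552 and 8020871 to 8023664. Joining peaks under 5 kb apart left 2483 regions. The share in the outer 25% at either chromosome end (the outer parts) was highest among the strongest regions: 69.7% of the best 621 joined regions lay there (66.0 to 73.2%), against 48.1% (44.2 to 52.1%) of the next 621, 53.9% (50.0 to 57.8%) of the 621 after them and 48.1% (44.2 to 52%) of the 620 weakest. Without joining, the 941 weakest peaks of the combined list had 52.4% (49.2 to 55.6%), an interval that includes 50%, whereas the weakest 694 peaks of replicate 1 had 57.5% (53.8 to 61.1%) and the weakest 226 of replicate 2 had 61.1% (54.6 to 67.2%). The 906 best replicate 1 peaks had 73.0% in the outer parts and the 906 of replicate 2 had 73.1%. Of the former, 701 overlap a peak of the latter, so these shares are not independent and no test result for their difference is given.

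The strongest regions of a replicate were often the ones another list lacked. Of the 50 best replicate 2 peaks, 68% (54.2 to 79.2%) were missing from the combined list, against 0.857% (0.292 to 2.49%) of ranks 51 to 400 (Fisher's exact test, p = 1.42e-33). Of the 23 best replicate 2 peaks that replicate 1 lacks, 0 (95% interval up to 14.3%) were in the combined list. This cannot decide on binding in 1 replicate only, since the combined list also lacked regions of both replicates. It lacked 11 of the 50 best replicate 1 peaks, whereas replicate 2 lacked 0 of those 50. A candidate explanation is that a region whose q-value rounds to 0 is left out of a list. Combined −log10 q was predicted from replicate 1 by a straight line fitted to the 2435 peaks matched one to one between these lists. The 11 of the 50 best replicate 1 peaks missing from the combined list had predicted values of 310 to 426. Of these, 9 passed the limit of 323 for double-precision numbers, against 1 of the 39 present ones. The present peaks are no control, since the line was fitted to listed peaks, whose combined −log10 q reached at most 322.5. Among the 50 best peaks of each replicate, 34 regions, all in the outer parts and 0 on X, are missing from the combined list. If rounding removed them, the 20 named regions would follow after them. Of the 34, 23 are also missing from replicate 1, where rounding was not checked. The weakest of these 23 had −log10 q of 106 in replicate 2, below the 148 of a replicate 2 peak that is present in replicate 1.

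The widest peak lay on chromosome II in all 3 lists. Per the WBcel235 gene table, ceh-38 lies on II, where 3 lists had their widest peak, and ceh-28 on X, where 0 had it. Reads of a ceh-28 fragment would lie on X, so these values argue against its extra copies as the source of the peak on II. For a tagged ceh-38 fragment the count decides neither for nor against extra copies, since the chromosome was known beforehand. Extra copies of a tagged fragment could give a wide region of moderate q, and the 300 other combined-list peaks with −log10 q from 15 to 25 had a median width of 630.5 bp and none exceeded 3922 bp, the width of a peak on X whose region, 8016623 to 8023673, was also the second widest peak of replicate 1 (7051 bp, q = 6.13e-27). For the widest peak, on chromosome II, the ratio of −log10 q of replicate 2 to replicate 1 was 1.44, the second highest of 780 pairs with a median of 0.397. This ratio decides on no explanation. The called region was 21868 bp wide in replicate 1 and 6927 bp in replicate 2, and q-values also depend on read depth. Neighbouring strong sites joined into 1 peak are argued against by the replicates. There its −log10 q was the lowest among the 20 widest peaks. It was 21.4 in replicate 1 (next lowest 21.6, median 159) and 30.9 in replicate 2 (next lowest 66.5, median 155). The combined list does not decide, since its 19.4 held place 17 among the 20 widest peaks (median 82.0). Binding of the factor near its own gene stays open. The gene content of the region was not determined, since input coverage and WS180 gene positions were not used here.

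Denser peaks at chromosome ends, a pattern of both ends together that the right end of IV (18.4%) and the left end of V (21%) did not show, were weighed against 3 technical explanations. Weak or chance calls are argued against, since the outer share was 71.2% (68.3 to 74.0%) in the best 942 peaks of the combined list and 52.4% (49.2 to 55.6%) in the weakest 941. Neighbouring peaks of 1 region counted more than once do not account for all of it: the share fell from 59.2% to 55% (53.0 to 56.9%) after joining, and the 69.7% in the best 621 joined regions argues against closely spaced strong regions alone. After joining, the excess lay mainly in these best regions, since the weaker groups had 48.1%, 53.9% and 48.1%. Repeats, read mappability and gene density along the chromosomes were not tested and stay open beside a preference of the tagged factor, which may be part of it. The design holds no other group, so no biological explanation was tested.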
